A study of Mus musculus with 24 samples.

How the data were processed

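Gene expression in the right lung lobe was measured on 24 whole-transcript arrays, each holding the RNA of a separate mouse. Per the labels' protocols, every mouse, WT included, drank doxycycline for 2 weeks, the lungs were homogenised fresh in a phenol-based reagent, RNA was purified on columns, and biotin-labelled target was made with the Ambion WT Expression kit. The labels gave the strain and genotype of each mouse, which set the 12 groups: 3 TG mice and 1 WT mouse in each of 129, A/J, AKR/J, BALB/cJ and C3H, and 2 TG and 2 WT mice in C57BL/6J. The sets of fibrosis-prone strains (A/J, AKR/J and C57BL/6J) and fibrosis-resistant strains (129, BALB/cJ and C3H) were taken from the series design. The fibrosis code in the sample labels, read by its own key, names the sets the other way round, and under that reading the sign of every prone minus resistant value below turns. The emphysema label was given for AKR/J and BALB/cJ (emphysema) and for 129 and C3H (no emphysema), and was empty for A/J and C57BL/6J.

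The deposited values were read as log2 intensities of probe sets, from their range of 3.41 to 14.75, since natural or common logarithms would place the highest value beyond what an array scanner records. The log base, the summarisation and normalisation methods, the software and the genome build are not given in the sources used here. Medians of the 24 arrays lay between 7.759 and 7.835, and the values were used without further scaling. The table was held in part. It had 25285 probe sets, the last of which had 2 of 24 values and was left out. Set against RefSeq's protein-coding genes (GRCm38.p6), it covered 76.1% to 91.7% of the genes on chromosomes 1 to 4 and 10 to 19, 26.3% on chromosome 5, and at most 2.0% on chromosomes 6 to 9 and X, where 88 genes were measured. Genes elsewhere, among them Tgfb1 and all sex-linked check genes, were not analysed here, so neither the transgene's own level nor the sex of the mice was checked. The reference served for gene names and coverage alone, and no coordinates are given.

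In the platform annotation, 14539 probe sets had 1 gene symbol, 781 had several and 9964 were unnamed here. Of the 14539, 14480 matched RefSeq by Entrez identifier, and 0 symbols changed. A gene with several probe sets (590 genes) was represented by the probe set of highest mean, which left 13499 genes, and in 1 of these genes the probe sets were called in opposite directions in TG against WT mice. Probe sets of paralogous genes can share sequence, so values for Nlrp1 family members, H2-Q genes, Gsta genes and chitinase-like genes are uncertain as to which copy was measured, and sequence variants between strains can change the binding of a probe.

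Tests were run with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. TG and WT mice were compared over all strains with strain as a fixed effect plus genotype (17 residual degrees of freedom). All other comparisons were contrasts of a fit with 12 group means (12 residual degrees of freedom), which shares a single estimate of the spread over all groups, so a lone WT mouse was assumed to vary like the other groups. Differences are given as log2 values ± SE, and p-values were adjusted by Benjamini and Hochberg's method within each comparison, with a threshold of 0.05. The strain carries the prone or resistant name, so the comparison of TG mice was run with mice as the unit, which speaks of these 6 strains alone, and with strain means as the unit. Of 43 gene lists (pathways, cell types, neighbouring tissues and checks), with 475 of 733 genes in the table, 41 were tested. The strain check genes were left out of the list tests, and the sex-linked list had 0 genes in the table. The lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way and does not compare them with other genes.

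The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for TG against WT, the 12 largest called changes each way with the same direction in all 6 strains. For prone against resistant TG mice it took up to 12 called genes each way with no overlap between the mice of the 2 sets, which gave 10 and 7. It took the 8 largest called values each way for the difference of TG effects, the 8 smallest p-values for strain dependence, the 6 largest each way with no overlap for the emphysema label and the 3 largest each way in each strain. Up to 4 members of largest change stand for a described list. A gene from outside the rule is said to be chosen after its values were seen.

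Array number limits the precision, and 5 of the 6 strains had 1 WT mouse. The 17 pairs of mice of the same group correlated at 0.9916 to 0.9972 across genes, the median residual SD was 0.104, and the closest pair still differed by a median of 0.084 per gene. The steps were tested on simulated data in which 200 of 13499 genes changed. At a log2 change of 0.5, 99% were recovered in TG against WT over all strains, 90% in the prone and 90% in the resistant strains, 96% in prone against resistant TG mice with mice as the unit and 36% with strains as the unit, 83% in WT mice, 93% for the emphysema label, 74% for the difference of TG effects and 6% for strain dependence. At a log2 change of 1 these shares were 100%, 99%, 97%, 100%, 82%, 98%, 99%, 98% and 71%. False calls made up 1.5% to 10.5% of calls. For prone against resistant TG mice with mice as the unit, WT mice and the emphysema label, the simulated strains did not differ from each other. With strains as the unit they did, so the 96% and 36% come from unlike settings. False calls from strain differences were therefore not counted for the mouse-level comparisons. A list shifted on purpose was called and 0 of the other lists were. The simulated genes varied independently of each other, so this does not test the preset correlation.

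Alternatives covered quantile normalisation, median centring, leaving out the dimmest 33% of genes, every probe set, the mean of a gene's probe sets, a trended and robust prior, array weights, a minimum of 2-fold, the replicate number as a block, other treatments of strain, each mouse and each strain left out, and, added after seeing the data, 3 mice left out together and a clock gene score as a covariate. Other divisions of the mice or strains, at most 100 per comparison, were refitted to count how often they called as many genes.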

Results

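Total RNA from the right lung lobe of 24 mice of 6 inbred strains was profiled on whole-transcript arrays, with 13499 genes read from the part of the table analysed here. Of the mice, 17 carried a transgene for TGF-β1 (TG), a cytokine that drives deposition of extracellular matrix, and 7 were wild type (WT). All 24 had been given doxycycline, the drug that switches the transgene on, for 2 weeks. The strains 129 (labelled S129), A/J, AKR/J, BALB/cJ and C3H had 3 TG mice and 1 WT mouse each, and C57BL/6J had 2 of each. The series asks which genes modify lung fibrosis under TGF-β1, and its design names A/J, AKR/J and C57BL/6J as prone and 129, BALB/cJ and C3H as resistant. A fibrosis code in the sample labels names the sets the other way round, and the series design was followed. Values were log2 intensities with array medians between 7.759 and 7.835, and the first 3 principal components held 27.1%, 14.5% and 10.3% of the variance.

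Strain labels were checked on H2-Ea, the MHC class II alpha chain gene that carries a promoter deletion in mice of the b haplotype. H2-Ea lay between 12.21 and 13.55 in the 16 A/J, AKR/J, BALB/cJ and C3H mice and between 6.27 and 6.90 in the 8 mice of 129 and C57BL/6J. Nnt, a mitochondrial transhydrogenase gene with a known deletion in C57BL/6J, lay between 9.58 and 9.62 in C57BL/6J and between 9.83 and 10.54 in the other strains. Hc, which encodes complement C5 and is defective in A/J and AKR/J, rose by 0.70 ± 0.12 in TG mice (limma adjusted p = 0.00012). The level of Hc did not set the TG mice of A/J and AKR/J (12.54 to 13.27) apart from those of the other strains (12.80 to 13.29). No sample stood against its strain label on H2-Ea or Nnt. Neither deletion tells A/J, AKR/J, BALB/cJ and C3H from each other, so a swap among these strains was not checked.

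Fabp7, a fatty acid binding protein of the brain type, rose most among the named genes, by 2.57 ± 0.23 (5.94-fold; 17 TG and 7 WT mice, limma adjusted p = 6.6e-08). Igf1, a growth factor, rose by 1.63 ± 0.12 (3.1-fold, adjusted p = 6.9e-09), and Itgb6, the epithelial integrin subunit that activates latent TGF-β, rose by 1.48 ± 0.11 (adjusted p = 2.5e-09). Matrix-associated Ltbp2 (1.54 ± 0.16), Tnc (1.49 ± 0.13) and Itgbl1 (1.47 ± 0.12) rose with them, as did the secreted proteins Lrg1 (1.56 ± 0.13) and Itih4 (1.49 ± 0.11), the receptor Ntrk2 (1.42 ± 0.14), Tnfsf18 (1.51 ± 0.21), which encodes the ligand of GITR, Pkhd1 (1.47 ± 0.17) and the transglutaminase Tgm1 (1.39 ± 0.11). Acoxl, an acyl-CoA oxidase-like gene, fell most, by 2.24 ± 0.23 (4.73-fold, adjusted p = 3.6e-07). Igfbp3, a carrier of IGF, fell by 1.77 ± 0.17, and Chia1, acidic chitinase, fell by 1.69 ± 0.22. Also lower were the channel genes Kcnj13 (-1.36 ± 0.13), Gabrp (-1.24 ± 0.10) and Lrrc26 (-1.23 ± 0.09), Pigr, the transporter of IgA (-1.23 ± 0.13), the detoxifying Gsta3 (-1.23 ± 0.18) and Aox3 (-1.19 ± 0.09), 1810010H24Rik (-1.28 ± 0.16) and Scel (-1.21 ± 0.18). Platelet chemokine gene Ppbp fell by 1.47 ± 0.34 (adjusted p = 0.0026), with the WT mouse of BALB/cJ at 12.58 and the next highest of the other mice at 10.33. Its change ran from -1.74 to -0.92 with a mouse or strain left out. In all, limma called 3601 of 13499 genes, 1785 higher and 1816 lower, 58 of them by at least 2-fold, and 1248 of the higher and 1180 of the lower genes moved the same way in all 6 strains.

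Collagens and their partners rose together in TG lungs. Of 16 measured, 14 rose and 1, Dcn (-0.20 ± 0.06), fell, with the same counts adjusted over the list alone, a median change of 0.40, and Lox, which crosslinks collagen, at 1.23 ± 0.13, Col1a1 at 1.02 ± 0.08, Col3a1 at 0.97 ± 0.06 and Vcan at 0.92 ± 0.16. The list passed camera (adjusted p = 4.7e-10) but not with its correlation estimated from the data (adjusted p = 0.12 with an estimated correlation). TGF-β targets and matricellular genes rose in 12 of 20 cases and fell in 1, Smad7 at -0.20 ± 0.07 (13 and 2 adjusted over the list alone). The TGF-β target list had camera adjusted p = 9.6e-07, and adjusted p = 0.12 with an estimated correlation. Among them Pmepa1, a feedback inhibitor of TGF-β signalling, rose by 1.23 ± 0.06 with the smallest adjusted p of all genes (7.5e-11), and Ccn2 rose by 0.66 ± 0.09. Proteases and their inhibitors rose in 9 of 16 cases and fell in 1, the cystatin gene Cst7 (the same adjusted over the list alone), led by Ctsk (1.15 ± 0.15), Mmp14 (1.00 ± 0.09), Serpina3n (0.83 ± 0.11) and Mmp19 (0.79 ± 0.18). By camera the protease list had adjusted p = 0.00015, and adjusted p = 0.12 with an estimated correlation.

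Epithelial lists moved apart. Of 9 genes of the transitional alveolar epithelium, a keratin-8-high state between type 2 and type 1 cells, 7 rose and 0 fell (8 adjusted over the list alone), with Sfn at 1.14 ± 0.14, Krt8 at 0.71 ± 0.07 and Krt18 at 0.60 ± 0.10 beside Itgb6. The transitional list had camera adjusted p = 5.1e-07, and adjusted p = 0.12 with an estimated correlation. Cytochrome P450 and airway detoxification genes fell in 7 of 8 cases, the same adjusted over the list alone, with Cyp4b1 at -1.19 ± 0.14, Aldh1a7 at -0.89 ± 0.07, Fmo1 at -0.73 ± 0.07 and Aldh3a1 at -0.70 ± 0.09, while Adh1 rose by 0.46 ± 0.08. By camera the P450 list had adjusted p = 4.6e-06, and adjusted p = 0.10 with an estimated correlation. Club and goblet cell genes fell in 5 of 11 cases, among them Gabrp, the secretoglobin Scgb3a2 (-0.65 ± 0.14) and Cbr2 (-0.62 ± 0.06), and Spdef rose by 0.12 ± 0.04 (the same adjusted over the list alone). The club list had camera adjusted p = 0.025, and adjusted p = 0.44 with an estimated correlation, and its score was not lower in every strain (-0.96 in A/J, -0.01 in C3H and 0.55 in 129). Ciliated cell genes fell in 4 of 15 cases (5 adjusted over the list alone), with Cfap43 at -0.36 ± 0.09 and Dnah9 at -0.33 ± 0.09. By camera the ciliated list had adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation.

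Vascular and heart muscle genes were lower in TG lungs. Of 18 endothelial genes, 14 fell and 0 rose (15 adjusted over the list alone), with the endothelin receptor Ednrb at -0.85 ± 0.14, the angiopoietin receptor Tek at -0.60 ± 0.06, Ramp2 at -0.49 ± 0.05 and Eng at -0.46 ± 0.05. The endothelial list had camera adjusted p = 1.2e-08, and adjusted p = 0.12 with an estimated correlation. Heart muscle genes, which in lung samples come from the muscle sleeve of the pulmonary veins or from heart tissue, fell in 6 of 10 cases (8 adjusted over the list alone), among them Myl7 (-0.92 ± 0.15), Myh6 (-0.91 ± 0.13), Actc1 (-0.87 ± 0.14) and Tnnt2 (-0.75). By camera the heart muscle list had adjusted p = 2e-05, and adjusted p = 0.20 with an estimated correlation. Clock genes were also lower, 4 of 9 (the same adjusted over the list alone), with Hlf at -0.62 ± 0.12 and Nr1d1 at -0.54 ± 0.12. The clock list had camera adjusted p = 0.0045, and adjusted p = 0.43 with an estimated correlation.

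Monocyte, interstitial macrophage and MHC class II genes rose in TG lungs, and T and NK cell genes fell. Monocyte and interstitial macrophage genes rose in 7 of 10 cases with 0 lower (8 adjusted over the list alone), with Ms4a7 at 1.04 ± 0.12, the complement genes C1qc at 0.97 ± 0.13 and C1qb at 0.86 ± 0.11, and Vcan as above. By camera the monocyte list had adjusted p = 5.6e-06, and adjusted p = 0.14 with an estimated correlation. Complement rose in 4 of 7 cases (6 adjusted over the list alone), and 3 of these 4 were the C1q genes of the macrophage list. The complement list had camera adjusted p = 7.4e-05, and adjusted p = 0.13 with an estimated correlation. In AKR/J the monocyte and complement scores rose by only 0.10 and 0.07, against 0.34 to 1.07 and 0.39 to 0.99 in the other strains. MHC class II genes rose in 7 of 9 cases (the same adjusted over the list alone), with the transactivator Ciita at 0.65 ± 0.07, H2-DMa at 0.58 ± 0.08 and H2-Ab1 at 0.57 ± 0.07. By camera the MHC class II list had adjusted p = 1.2e-05, and adjusted p = 0.12 with an estimated correlation. T and NK cell genes fell in 7 of 9 cases (the same adjusted over the list alone), with the interleukin receptor Il2rb at -0.61 ± 0.10, the granzyme Gzma at -0.58 ± 0.16 and the chemokine receptor Ccr7 at -0.58 ± 0.10. The T and NK list had camera adjusted p = 0.00015, and adjusted p = 0.13 with an estimated correlation. Chemokines and cytokines rose in 10 of 24 cases and fell in 1, Cxcl15 (11 and 3 adjusted over the list alone), with Il6 at 0.82 ± 0.18, Cxcl14 at 0.72 ± 0.15 and Il1b at 0.65 ± 0.15. By camera the chemokine list had adjusted p = 0.011, and adjusted p = 0.14 with an estimated correlation.

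Of 23 cell cycle genes, 18 rose and 0 fell, the same adjusted over the list alone, with the cyclin Ccna2 at 0.90 ± 0.17, the kinase Cdk1 at 0.82 ± 0.15, the topoisomerase Top2a at 0.77 ± 0.14 and Nusap1 at 0.66. The cell cycle list had camera adjusted p = 7.3e-08, and adjusted p = 0.36 with an estimated correlation. Genes of endoplasmic reticulum stress rose in 6 of 14 cases and fell in 1, Chac1 (9 and 1 adjusted over the list alone), with the chaperones Pdia6 at 0.33 ± 0.06 and Hspa5 at 0.31 ± 0.07. By camera the ER stress list had adjusted p = 0.0021, and adjusted p = 0.25 with an estimated correlation. Of the 41 lists, 17 passed camera with the preset correlation and 0 with an estimated correlation, and fry, which compares no list with other genes, passed 22.

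**Figure D1:**
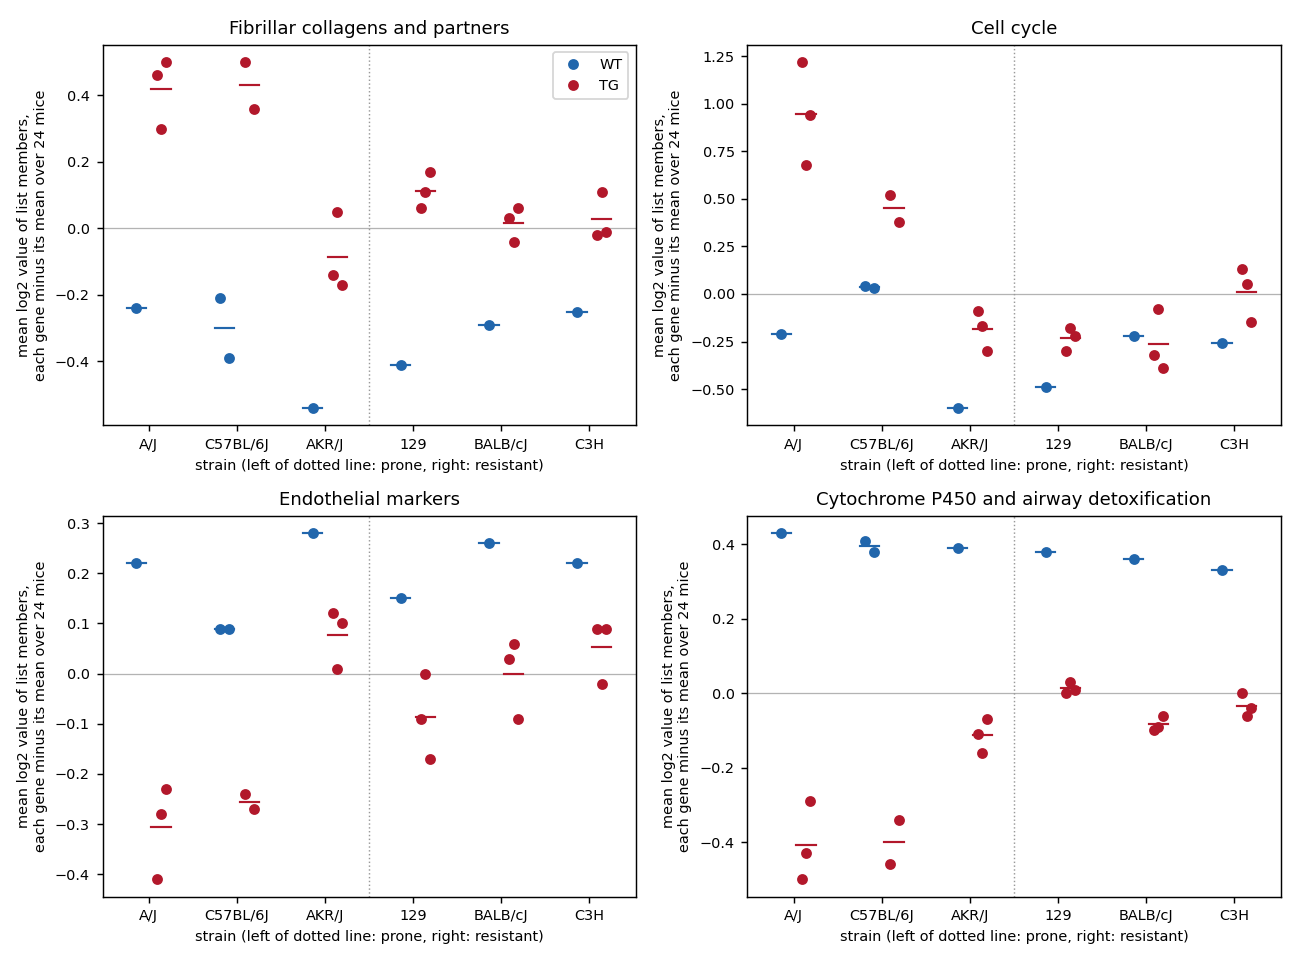
Mean log2 value of 4 gene lists in each of the 24 mice, each gene taken minus its mean over all mice, by strain on the horizontal axis, with TG mice in red, WT mice in blue and lines at the group means. Collagen genes were higher in TG than WT means in all 6 strains (0.28 in C3H to 0.73 in C57BL/6J), and cell cycle genes rose most in A/J (1.16) and lay at -0.04 in BALB/cJ.

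In the prone strains Col1a1 rose by 1.25 ± 0.09 and in the resistant strains by 0.77 ± 0.09, Lox by 1.41 ± 0.13 and 0.99 ± 0.14, and Itgb6 by 1.79 ± 0.09 and 1.16 ± 0.09. Cyp4b1 changed by -1.53 ± 0.10 in the prone and -0.74 ± 0.11 in the resistant strains, and Gsta3 by -1.69 ± 0.14 and -0.65 ± 0.15. The difference between the sets passed limma for Itgb6, Cyp4b1 and Gsta3 and not for Col1a1 or Lox. Limma called 3172 genes in the prone strains (1621 higher, 1551 lower) and 1444 in the resistant strains (664 higher, 780 lower). Of these, 1114 were called in both, where independent lists would share 339, and 1108 of the 1114 went the same way. Across genes, which are not independent replicates, the effects in the 2 sets correlated at 0.74. Collagen genes rose in 14 of 16 cases in the prone (14 with 1 lower adjusted over the list alone, camera adjusted p = 1.2e-11, adjusted p = 0.081 with an estimated correlation) and in 8 of 16 in the resistant strains (9 adjusted over the list alone, camera adjusted p = 5.6e-09, adjusted p = 0.090 with an estimated correlation). Cell cycle genes rose in 18 of 23 cases in the prone strains (20 adjusted over the list alone), with Ccna2 at 1.33 ± 0.16 (camera adjusted p = 8.6e-15, adjusted p = 0.11 with an estimated correlation). In the resistant strains 1 of 23, Aurka, rose (0 adjusted over the list alone), where Ccna2 was at 0.48 ± 0.17 and short of the threshold (camera adjusted p = 0.0021, adjusted p = 0.70 with an estimated correlation).

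By strain, limma called 2009 genes in A/J (918 higher, 1091 lower) and 1937 in C57BL/6J (940 higher, 997 lower), against 398 in 129, 305 in BALB/cJ, 285 in AKR/J and 111 in C3H. With array weights A/J called 471, BALB/cJ 172 and AKR/J 86. With 1 TG mouse left out the count fell as far as 903 in C57BL/6J (TG 1), 226 in 129 (TG 3), 167 in AKR/J (TG 1), 142 in BALB/cJ (TG 1) and 16 in C3H (TG 2). In simulated data a log2 change of 0.5 was recovered in 69% of genes in C57BL/6J, which had 2 WT mice, and in 44% to 58% in the other strains. In A/J the leading genes were Fabp7 (2.39 ± 0.50), Igf1 (2.39 ± 0.23) and Tnfsf18 (2.37 ± 0.49) upward and Igfbp3 (-2.58 ± 0.36), Pigr (-2.18 ± 0.27) and Ppbp (-2.16 ± 0.38) downward. C57BL/6J had Pkhd1 (2.55 ± 0.25), Ltbp2 (2.53 ± 0.20) and Fabp7 (2.45 ± 0.43) highest and Acoxl (-3.40 ± 0.42), Gsta3 (-2.29 ± 0.22) and Igfbp3 (-2.25 ± 0.31) lowest. In AKR/J, Fabp7 rose by 3.60 ± 0.50, Itgb6 by 2.09 ± 0.16 and Itih4 by 1.79 ± 0.24, and Chia1 (-2.51 ± 0.50), Igfbp3 (-1.56 ± 0.36) and Lrat (-1.54 ± 0.36) fell. In 129, Fabp7 (2.77 ± 0.50), Lrg1 (2.25 ± 0.25) and the airway secretory gene Bpifb1 (2.24 ± 0.42) led, and Acoxl (-2.38 ± 0.48), Chia1 (-2.03 ± 0.50) and the small nuclear RNA Scarna13 (-1.79 ± 0.14) fell. The Scarna13 value rests on the 129 WT mouse, at 11.25 against 9.42 to 9.51 in the TG mice. BALB/cJ had Fabp7 (3.07 ± 0.50), Steap4 (1.60 ± 0.27) and Ltbp2 (1.38 ± 0.23) highest, and its lowest values, Ppbp (-4.44 ± 0.38) and Rgs18 (-2.45 ± 0.28), both platelet genes, were set against its single WT mouse, with Acoxl next (-2.32 ± 0.48). In C3H, Ntrk2 (2.03 ± 0.34), Lrg1 (1.70 ± 0.25) and Itgbl1 (1.48 ± 0.32) rose and the fatty acid carrier Fabp4 (-1.91 ± 0.37), Igfbp3 (-1.71 ± 0.36) and the endothelial gene Esm1 (-1.45 ± 0.17) fell. Fabp4 is also a gene of fat cells, and the C3H WT mouse had the highest adipose score of all mice (1.29, the next 0.65), so its Fabp4 value may come from fat in that 1 sample. On genes called in the other 5 strains, the mean change in the called direction was 0.408 ± 0.028 (SD, n = 3 TG mice) in A/J, 0.389 ± 0.028 (n = 2) in C57BL/6J, 0.272 ± 0.042 (n = 3) in 129, 0.244 ± 0.021 (n = 3) in BALB/cJ, 0.192 ± 0.048 (n = 3) in AKR/J and 0.188 ± 0.042 (n = 3) in C3H. The differences between single strains in this mean were not tested, 5 strains rest on 1 WT mouse, and prone AKR/J lay below resistant 129 and BALB/cJ.

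**Figure D2:**
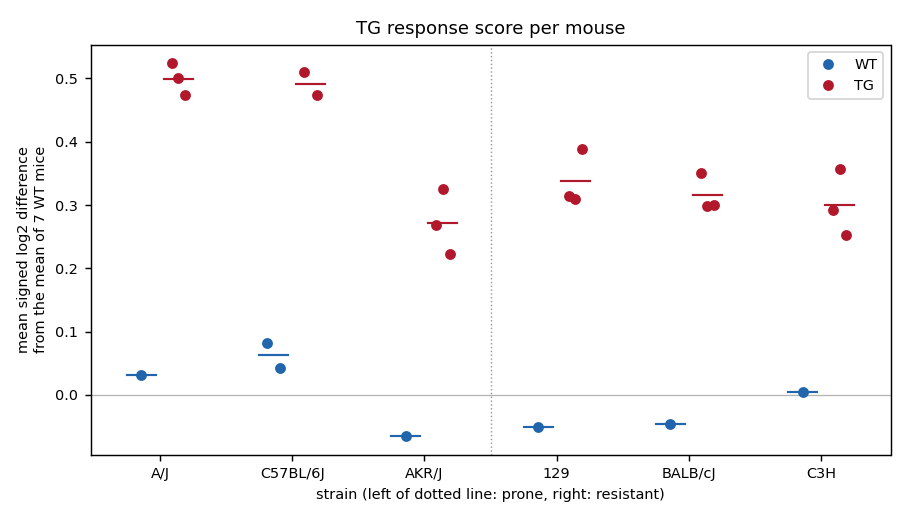
Response score of each mouse, the mean signed log2 difference from the mean of the 7 WT mice over 1849 genes called in TG against WT mice of AKR/J, 129, BALB/cJ and C3H, by strain on the horizontal axis, with TG mice in red, WT mice in blue and lines at the group means. The A/J and C57BL/6J TG mice lay at 0.474 or higher, the other TG mice at 0.388 or lower, and WT mice between -0.065 and 0.082.

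TG mice of the prone strains, compared directly with TG mice of the resistant strains, had less Lrat and Vipr2 and more Nlrp1 family signal. Lrat, which esterifies retinol for storage, differed by -1.41 ± 0.15 (limma adjusted p = 2.9e-05; 8 prone and 9 resistant mice), with 9.25 to 11.19 in prone and 11.24 to 12.45 in resistant mice. Vipr2, a receptor for vasoactive intestinal peptide, differed by -1.26 ± 0.08 (adjusted p = 1e-07), with 8.23 to 9.26 against 9.75 to 10.31. Nlrp1c-ps (1.25 ± 0.16) and the inflammasome gene Nlrp1a (0.70 ± 0.10) were higher, though which copy of this family each probe set measures is uncertain. Nlrp1c-ps reached 8.31 in C57BL/6J and 8.3 in A/J, but AKR/J (6.31 to 6.36) lay just above the resistant mice (5.88 to 6.26). For Nlrp1a, C57BL/6J (5.57) lay just above the resistant mice (5.06 to 5.34). These C57BL/6J and resistant Nlrp1a values were low, under the lower quartile of every array (6.243 or higher). Smaller differences without overlap were seen for Sp6 (0.40 ± 0.06), Sh3rf3 (0.28 ± 0.05), 1810055G02Rik (0.26 ± 0.04), Col18a1, a basement membrane collagen (0.25 ± 0.05), Map1a (0.22), Mcfd2 (0.21), Snx9 (0.18) and Dnajc25 (0.14) upward and Rfesd (-0.29), Acadm, which oxidises medium-chain fatty acids (-0.28), Ezh1 (-0.25), Rps20 (-0.23) and Sqor (-0.20) downward. These 17 genes were all that separated the mice of the 2 sets, where chance gives 0.00823% of genes, or 1.11, for independent mice, and the other 9 divisions of the 6 strains into sets of 3 separated 6 to 63 genes. With mice as the unit limma called 1503 genes (870 higher, 633 lower), 10 by at least 2-fold. With the strain as the unit, which is the replicate of the prone or resistant name, limma called 0 genes, with 518 at an unadjusted p under 0.05 where chance gives 675, so the mouse-level calls speak of these 6 strains alone.

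Of 23 cell cycle genes, 21 were higher and 0 lower in the TG mice of the prone strains (22 adjusted over the list alone), with a median of 0.59, the checkpoint kinase Bub1 at 0.98 ± 0.13, Top2a at 0.88 ± 0.10, the motor Kif11 at 0.87 ± 0.10 and Cdk1 at 0.82 ± 0.10 (camera adjusted p = 1.1e-23, adjusted p = 0.18 with an estimated correlation). By strain, the list's score in TG mice lay above the resistant mean by 1.11 ± 0.10 in A/J and 0.62 ± 0.12 in C57BL/6J, and AKR/J lay at -0.02 ± 0.10. Collagen genes were higher in 8 of 16 cases (11 adjusted over the list alone), with Col1a1 at 0.51 ± 0.07 and Col5a2 at 0.42 ± 0.07. The collagen list had camera adjusted p = 4.1e-06, and adjusted p = 0.25 with an estimated correlation. TGF-β targets were higher in 7 of 20 cases (11 adjusted over the list alone), with Ltbp2 at 0.87 ± 0.10, Tnc at 0.55 ± 0.13 and Cthrc1 at 0.47 ± 0.07. By camera the TGF-β target list had adjusted p = 3.8e-05, and adjusted p = 0.23 with an estimated correlation. Monocyte and interstitial macrophage genes were higher in 7 of 10 cases, the same adjusted over the list alone, led by Ms4a7 (0.63 ± 0.07) and C1qb (0.55 ± 0.08), with camera adjusted p = 4.1e-06 and adjusted p = 0.23 with an estimated correlation. Complement genes were higher in 4 of 7 cases, the same adjusted over the list alone, 3 of them C1q genes (camera adjusted p = 0.00088, adjusted p = 0.23 with an estimated correlation). AKR/J, though prone, had the lowest TG mean of the 6 strains for the monocyte (-0.35), complement (-0.38) and collagen (-0.09) lists, so these 3 differences lay in A/J (0.75, 0.74 and 0.42) and C57BL/6J (0.59, 0.52 and 0.43). Without A/J the complement median was 0.00. Transitional epithelial genes were higher in 2 of 9 cases, Sfn (0.55 ± 0.10) and Itgb6 (0.44 ± 0.07), the same adjusted over the list alone. Their scores were high in the TG mice of A/J (0.52 to 0.63) and C57BL/6J (0.40 and 0.34). Prone AKR/J (-0.17 to 0.14) lay below or among resistant C3H (0.08 to 0.43). The transitional list had camera adjusted p = 0.0037, and adjusted p = 0.43 with an estimated correlation.

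Endothelial and heart muscle genes were lower in the TG mice of A/J (list scores -0.31 and -0.50) and C57BL/6J (-0.26 and -0.65), while those of prone AKR/J had the highest scores of the 6 strains (0.08 and 0.16). Over the prone set, endothelial genes were lower in 7 of 18 cases and higher in 1, Nos3 (11 and 1 adjusted over the list alone), with Ednrb at -0.65 ± 0.08 and Ramp2 at -0.36 ± 0.05. By camera the endothelial list had adjusted p = 2.9e-07, and adjusted p = 0.23 with an estimated correlation. Cytochrome P450 and detoxification genes were lower in 5 of 8 cases, the same adjusted over the list alone, with Cyp4b1 at -0.76 ± 0.08 and Fmo2 at -0.55 ± 0.08. The P450 list had camera adjusted p = 4.3e-05, and adjusted p = 0.082 with an estimated correlation. Its scores in TG mice of prone AKR/J (-0.16 to -0.07) overlapped those of resistant BALB/cJ (-0.10 to -0.06). Ciliated cell genes were lower in 4 of 15 cases (8 adjusted over the list alone), with Sntn at -0.53 ± 0.14 (camera adjusted p = 3.8e-05, adjusted p = 0.48 with an estimated correlation). Resistant BALB/cJ had ciliated scores of -0.23 to -0.07 in TG mice, overlapping prone AKR/J (-0.25 to -0.13) and C57BL/6J (-0.12 and -0.11). T and NK cell genes were lower in 4 of 9 cases, the same adjusted over the list alone, with Gzma at -0.45 ± 0.14 (camera adjusted p = 0.0038, adjusted p = 0.44 with an estimated correlation). TG mice of resistant 129 had T and NK scores of -0.22 to -0.16, beside prone C57BL/6J (-0.16 and -0.14) and AKR/J (-0.39 to -0.03). Heart muscle genes moved with these groups, lower in 4 of 10 cases (5 adjusted over the list alone), with Myl7 at -0.84 ± 0.14 and Myl4 at -0.64 ± 0.10. By camera the heart muscle list had adjusted p = 0.0001, and adjusted p = 0.41 with an estimated correlation. Alveolar type 2 genes were lower in 1 of 16 cases, Lyz1 (-0.52 ± 0.13), the same adjusted over the list alone. Type 2 scores were low in C57BL/6J TG mice (-0.36 and -0.10), while prone A/J (-0.09 to 0.35) reached above the resistant strains (-0.04 to 0.11). The list's median lay between -0.15 and 0 with a mouse or strain left out. The type 2 list had camera adjusted p = 0.0072, and adjusted p = 0.64 with an estimated correlation. Of 11 neutrophil genes 0 passed, also adjusted over the list alone, with a median of -0.52, with S100a8 at 10.96 in TG mouse 1 of 129 and at 7.9 in the next highest mouse. This median ran from -0.86 to -0.19 with a mouse or strain left out. By camera the neutrophil list had adjusted p = 0.0099, and adjusted p = 0.55 with an estimated correlation.

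In WT mice, Chil1, a chitinase-like gene, was higher in the prone strains by 1.13 ± 0.11 (4 prone and 3 resistant mice, limma adjusted p = 3.4e-05), airway secretory Bpifb1 by 1.76 ± 0.28 (adjusted p = 0.0051) and complement C4b by 0.70 ± 0.10 (adjusted p = 0.0024), while Chil3, made by alveolar macrophages, was lower, at -2.25 ± 0.46 (adjusted p = 0.029). For Chil3 the A/J WT mouse was at 4.91 and the other 6 WT mice were between 9.14 and 10.84, so the difference rests on A/J. The A/J TG mice were low too, at 5.34 to 7.1, where the other TG mice lay between 7.26 and 10.31. Among genes chosen after their values were seen, the serotonin receptor Htr2b was lower, at -1.28 ± 0.12, and the non-coding AI506816 higher by 3.25 ± 0.40. Limma called 100 genes (55 higher, 45 lower). Of the 17 separating genes above, 13 had the same sign in WT mice, and Nlrp1a (1.65 ± 0.15), Sp6 (0.66 ± 0.09), Mcfd2 (0.29 ± 0.05) and Vipr2 (-0.69 ± 0.12) were called there too, whereas Lrat was at -0.02 ± 0.25. Of the 1503 genes called in TG mice, 1047 (69.7%) had the same sign in WT mice, and 61 were called the same way, out of 62 called in both where independent lists would share 11.1. In WT mice 0 of 23 cell cycle genes passed (score 0.06 ± 0.12), with C57BL/6J at 0.36 ± 0.14 and AKR/J at -0.28 ± 0.18 from the resistant WT mice. Complement was higher in 1 of 7 cases (5 with 1 lower adjusted over the list alone, camera adjusted p = 7.5e-05, adjusted p = 0.22 with an estimated correlation), club and goblet genes in 1 of 11 (6 adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.22 with an estimated correlation) and interferon genes in 0 of 11 (5 adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.56 with an estimated correlation). The other lists past camera were MHC class I, monocyte, ciliated, alveolar macrophage and adipose genes, none with an estimated correlation (adjusted p = 0.24 or higher). In all, 8 lists passed camera and 0 with an estimated correlation. Each prone or resistant mean rests on 1 or 2 WT mice per strain, so these are differences between the 6 strains that cannot be laid to the sets, and the count lay between 30 and 254 when a mouse or a strain was left out.

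Few genes passed limma for a difference of the TG effect itself between prone and resistant strains. Lrat fell in A/J, AKR/J and C57BL/6J (-1.53, -1.54 and -1.67) and lay at -0.33, 0.00 and -0.23 in 129, BALB/cJ and C3H, a difference of -1.39 ± 0.29 (limma adjusted p = 0.043). The xenobiotic enzyme Cyp4b1 fell more over the prone set (-0.79 ± 0.15), as did Gsta3 (-1.03 ± 0.20) and 1810010H24Rik (-1.09 ± 0.15, limma adjusted p = 0.0092). In each case A/J and C57BL/6J were at -1.78 or lower. AKR/J was at -0.73 for Cyp4b1 and -0.70 for Gsta3, among the resistant strains (-0.76 to -0.70 and -0.76 to -0.54). For 1810010H24Rik AKR/J was at -1.07, below the resistant strains (-0.88 to -0.46). Bpifb1 rose in 129 (2.24), was at 0.95 and 0.85 in BALB/cJ and C3H without passing there, and lay at -0.91 to 0.29 in the prone strains. The difference for Bpifb1 was -1.66 ± 0.33 (limma adjusted p = 0.039). In level, Bpifb1 lay at 11.13 to 12.49 in the prone and 9.37 to 10.47 in the resistant WT mice. The TG mice overlapped, at 9.93 to 12.67 and 10.4 to 11.99, so this difference rests on the WT mice. Also negative were Nlrp1a (-0.95 ± 0.18), H2-Q5 (-0.83 ± 0.14), both of families with similar copies, and the lymphoid chemokine gene Ccl19 (-0.73 ± 0.15). Nlrp1a was at -1.67 in A/J and at 0.02 in C57BL/6J, among the resistant strains (-0.05 to 0.24), and Ccl19 was at 1.15 in 129 and at most 0.20 elsewhere. The Nlrp1a difference was -0.54 without A/J or its WT mouse and -1.39 without C57BL/6J. That of Ccl19 was -0.41 without 129 or its WT mouse, and neither -0.54 nor -0.41 passed. In level, Nlrp1a was higher in the prone set by 1.65 ± 0.15 in WT mice and by 0.70 in TG mice, so its negative value rests on the WT mice. Positive differences were found for Htr2b (0.87 ± 0.14, adjusted p = 0.018), 4 genes of mitosis, Knstrn (0.87 ± 0.14), Racgap1 (0.85 ± 0.14), Ncapg2 (0.73 ± 0.14) and Hmmr (0.70 ± 0.13), the adhesion gene Nrcam (0.83 ± 0.17), the laminin gene Lama1 (0.79 ± 0.16) and Esm1 (0.69 ± 0.14). The 4 mitosis genes were at 1.2 to 1.53 in A/J and at 0.30 to 0.67 in AKR/J and C57BL/6J, and without A/J or its WT mouse their differences were 0.59, 0.52, 0.46 and 0.32, none passing. For Lama1 and Esm1 this held for A/J (1.57 and -0.67) and C57BL/6J (1.85 and -0.38), while AKR/J (0.13 and -1.46) lay below or among the resistant strains (0.32 to 0.47 and -1.57 to -1.45). Without C57BL/6J the values of Lama1, Esm1, Cyp4b1 and Gsta3 were 0.45, 0.46, -0.51 and -0.73, and none passed, and without AKR/J or its WT mouse Lama1 was at 1.31 and Cyp4b1 at -1.2. Each of the 16 genes named here lost its call in at least 1 of the 30 fits with a mouse or strain left out. Their calls held in 7 (Nrcam) to 26 (1810010H24Rik) of these fits, and those of Lrat and Bpifb1 in 8. Limma called 64 genes (34 higher, 30 lower), and the count ranged from 1 to 425 when a mouse or a strain was left out. At an unadjusted limma p under 0.05 there were 1553 genes where chance gives 675, so few calls do not mean few differences. With the 6 strains' own differences as the unit, 1 gene was called.

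By list, the TG effect on cell cycle genes was larger in the prone set by a median of 0.51, which was 0.28 without A/J or its WT mouse and 0.64 without AKR/J or its WT mouse. The list score rose by 1.16 in A/J, against 0.41 in AKR/J, 0.42 in C57BL/6J and -0.04 to 0.26 in the resistant strains. Of 23 genes 1, Bub1b (0.50 ± 0.09), passed (19 adjusted over the list alone), with camera adjusted p = 4.1e-17 and adjusted p = 0.22 with an estimated correlation. Cytochrome P450 and detoxification genes fell more in A/J (score -0.84) and C57BL/6J (-0.80), with AKR/J at -0.50 near BALB/cJ (-0.44). In the difference between the sets 1 of 8, Cyp4b1, passed (5 adjusted over the list alone), and this list held under both settings. The P450 list had camera adjusted p = 4.9e-06, and adjusted p = 0.035 with an estimated correlation. Ciliated genes had a median of -0.35 with 0 of 15 passing (9 adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.25 with an estimated correlation). The ciliated score changed by -0.52 in A/J and -0.38 in C57BL/6J. In AKR/J it changed by -0.08, among the resistant strains (-0.12 to 0.07). Club and goblet genes had a median of -0.43, which was -0.22 without A/J or its WT mouse, with 1 of 11, Bpifb1, passing (3 adjusted over the list alone, camera adjusted p = 7.3e-07, adjusted p = 0.055 with an estimated correlation). The club score changed by -0.96 in A/J and 0.55 in 129 and lay between -0.32 and -0.01 in the other 4 strains. For collagen genes the median was 0.26, which was 0.16 without C3H or its WT mouse, with 0 of 16 passing (7 adjusted over the list alone). By camera the collagen list had adjusted p = 7.5e-06, and adjusted p = 0.25 with an estimated correlation. Smaller shifts passed camera for endothelial, MHC class I, TGF-β target, transitional epithelial, interferon, protease, alveolar type 2, heart muscle and lipid synthesis lists, none of them with an estimated correlation (adjusted p = 0.22 or higher). Altogether 14 lists passed camera, 1 with an estimated correlation and 2 by fry.

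Over the 6 strains without regard to set, 181 genes had TG effects that differed. This count was 52 with array weights and 59 to 350 with a mouse or strain left out, without C57BL/6J and without TG mouse 3 of A/J respectively. The 8 of smallest p are named here. Scarna13 changed by -1.91 in A/J and -1.79 in 129 and lay between -0.25 and 0.09 elsewhere (range 2.01, limma adjusted p = 8.4e-05). The Wnt inhibitor gene Dkk2 rose by 1.15 in C57BL/6J and lay between -0.15 and 0.12 in the others (range 1.31, adjusted p = 0.0014), Spock2 rose by 0.98 in AKR/J (range 1.2), and the mast cell protease Mcpt4 changed by -1.18 in C3H (range 1.09). The range was 0.28 for Dkk2 without C57BL/6J, 0.54 for Spock2 without AKR/J or its WT mouse and 0.32 for Mcpt4 without C3H or its WT mouse, and none of these passed. F5 (-1.38), P2ry12 (-1.45) and Ppbp (-4.44), genes expressed in megakaryocytes and platelets, were lowest in BALB/cJ (ranges 1.82, 1.67 and 4.36). With 3 mice left out, the WT mouse of BALB/cJ among them, an alternative chosen after seeing the data, the ranges of F5, P2ry12 and Ppbp were 0.51, 0.13 and 2.08 and none passed. Sox2, a factor of airway epithelium, ranged from -0.68 in A/J to 0.61 in 129 (range 1.29, adjusted p = 0.0042). Of the 8, only Scarna13 passed with each single mouse or strain left out. Its effects rest on the single WT mice of 129 (11.25) and A/J (10.8), where all other mice lay between 8.64 and 9.51. Leaving out 1 of these WT mice kept the other in the fit.

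TG mice of the strains with the emphysema label, AKR/J and BALB/cJ, were compared with those of 129 and C3H. Veph1 (1.61 ± 0.18, limma adjusted p = 5.6e-05), 4833420G17Rik (0.90 ± 0.07), the retinoid-responsive Rarres1 (0.86 ± 0.12), Dubr (0.84 ± 0.08), Fbxo44 (0.76 ± 0.11) and Gm5148 (0.76 ± 0.10) were higher. The adhesion gene Cntn1 (-1.74 ± 0.16, adjusted p = 1e-05), the keratin gene Krt79 (-1.38 ± 0.32), the uroplakin gene Upk1b (-1.38 ± 0.09), the glycine receptor Glrb (-1.30 ± 0.08), Htr2b (-1.13 ± 0.09) and ciliated cell gene Sntn (-1.13 ± 0.16) were lower. With a mouse or strain left out Cntn1 ran from -2.41 to -1.08 and Krt79 from -1.9 to -0.87. WT mice were not compared by this label, so these differences cannot be laid to the transgene. Cntn1 in WT mice lay at 6.74 in AKR/J, 7.64 in BALB/cJ, 9.41 in 129 and 8.66 in C3H. Over these strains TG effects ran from -0.37 to -0.03 for 4833420G17Rik, -0.26 to -0.12 for Gm5148 and -0.18 to 0.16 for Rarres1. Other TG effects were unequal, with Upk1b at 1.05 in C3H, Fbxo44 at 0.67 in AKR/J and Sntn at -0.37 in AKR/J and 0.07 in C3H. Limma called 965 genes (398 higher, 567 lower), and 120 were above and 185 below in every mouse of 6 against 6. Over all genes, called or not, 367 did not overlap, where chance gives 0.216%, or 29.2 genes, for independent mice. The mice of a strain are not independent, and the comparison sets 2 strains against 2. The count of 965 fell to 416 without AKR/J, to 467 without 129 and to 168 with a clock gene score as a covariate, added after seeing the data. Clock genes were higher in 8 of 9 cases (9 adjusted over the list alone), with Per3 at 0.98 ± 0.20, Hlf at 0.94 ± 0.15 and Per2 at 0.85 ± 0.21. Among the BALB/cJ TG mice, mouse 3 had a clock score of 0.75 and mice 1 and 2 were at -0.33 and -0.13, beside 129 and C3H (-0.49 to -0.13), so the difference lay in AKR/J and that mouse. The clock list had camera adjusted p = 1.9e-08, and adjusted p = 0.41 with an estimated correlation.

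Some immune and epithelial lists were lower with the emphysema label by camera at the preset correlation. Ciliated genes were lower in 6 of 15 cases (10 adjusted over the list alone), with Dnah9 at -0.42 ± 0.08. By camera the ciliated list had adjusted p = 6.4e-07, and adjusted p = 0.41 with an estimated correlation. Alternatively activated macrophage genes were lower in 3 of 12 (4 adjusted over the list alone), with Retnla at -1.76 ± 0.36 and Chil3 at -1.51 ± 0.34 (camera adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation). Retnla lay at 8.04 to 8.91 in the TG mice of AKR/J and BALB/cJ, at 10.32 to 11.3 in 129 and at 9.05, 11.29 and 8.46 in C3H. Most of its difference thus lay in 129, whose WT mouse was at 10.52, and in 1 C3H mouse. Alveolar macrophage genes were lower in 3 of 8, the same adjusted over the list alone, with Marco at -0.41 ± 0.10 (camera adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation). Neutrophil genes were lower in 1 of 11, Retnlg (-1.43 ± 0.41; 2 adjusted over the list alone), with TG mouse 1 of 129 at 11.42. The neutrophil list had camera adjusted p = 0.00014, and adjusted p = 0.41 with an estimated correlation. MHC class II genes were lower in 4 of 9, with H2-Ab1 at -0.66 ± 0.08, and higher in 1, H2-Ea (3.38 ± 0.08), whose transcript is lacking in 129 (6 and 1 adjusted over the list alone), with a negative median, a positive mean and a downward camera test (adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation). Transitional epithelial genes were lower in 3 of 9 (6 adjusted over the list alone), with Sprr1a at -0.63 ± 0.15. By camera the transitional list had adjusted p = 0.0032, and adjusted p = 0.41 with an estimated correlation. The Wnt list was higher in 3 of 19 (5 adjusted over the list alone), with Lgr6 at 0.68 ± 0.08. The Wnt list had camera adjusted p = 0.047, and adjusted p = 0.41 with an estimated correlation. Cell cycle genes were lower in 2 of 23, Ccna2 and Pcna, the same adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.75 with an estimated correlation). Collagens were lower in 1 of 16, Lox (0 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.72 with an estimated correlation), and blood genes passed in 0 of 5, also adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.41 with an estimated correlation). Of the 41 lists, 11 passed camera, 0 with an estimated correlation and 3 by fry.

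**Figure D3:**
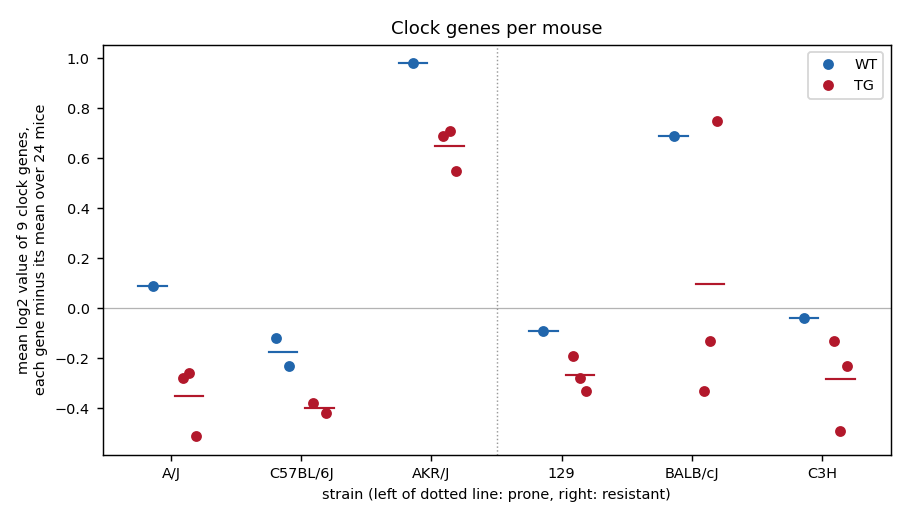
Mean log2 value of 9 clock genes in each of the 24 mice, each gene taken minus its mean over all mice, by strain on the horizontal axis, with TG mice in red, WT mice in blue and lines at the group means. The 4 AKR/J mice (0.55 to 0.98), TG mouse 3 of BALB/cJ (0.75) and the WT mouse of BALB/cJ (0.69) lay above all other mice (-0.51 to 0.09).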

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

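The 64 and 181 genes below come from planned comparisons. Apart from the time of day at harvest, the tests of explanations and the other divisions of the mice were chosen only after the result was seen.

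Genes were singled out here because the size of the TG effect was not the same in all groups of strains. Limma found 64 such genes between the prone and resistant sets. The positive ones named were Htr2b (0.87), Knstrn (0.87), Racgap1 (0.85), Nrcam (0.83), Lama1 (0.79), Ncapg2 (0.73), Hmmr (0.70) and Esm1 (0.69). The negative ones were Bpifb1 (-1.66), Lrat (-1.39), 1810010H24Rik (-1.09), Gsta3 (-1.03), Nlrp1a (-0.95), H2-Q5 (-0.83), Cyp4b1 (-0.79) and Ccl19 (-0.73). Over the 6 strains 181 genes differed, and the named ones spanned 2.01 (Scarna13), 1.31 (Dkk2), 1.82 (F5), 1.09 (Mcpt4), 1.67 (P2ry12), 1.2 (Spock2), 1.29 (Sox2) and 4.36 (Ppbp). Probe sets without a single gene name were left out of all lists, and 376 of these 10745 passed limma in TG against WT mice (236 higher, 140 lower).

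Cell cycle genes were higher in TG mice of the prone strains, by 0.57 ± 0.08 in list score, and the TG effects differed by 0.50 ± 0.14. For A/J a baseline difference was excluded as the whole reason, since its TG effect lay 1.00 ± 0.21 above that of the resistant strains. For C57BL/6J it stays open, since its WT mice already lay 0.36 ± 0.14 above the resistant ones and its TG effect 0.26 ± 0.19 above theirs. Whether AKR/J stands outside the pattern stays open too, since its TG mice lay at -0.02 ± 0.10 from the resistant mean and its TG effect, set against a low WT mouse, 0.25 ± 0.21 above theirs.

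Clock genes stood apart in AKR/J and in 2 of the 4 BALB/cJ mice. TG mouse 3 of BALB/cJ (0.75) lay 0.98 above the mean of TG mice 1 and 2 of its own strain (-0.33 and -0.13). The other TG groups ranged over at most 0.36 from lowest to highest mouse. For AKR/J, whose lowest mouse lay 0.47 above the highest mouse of the 4 strains other than BALB/cJ, strain and day of harvest cannot be told apart. The time of day at harvest could not be told, since Nfil3, the 1 gene of opposite phase measured, had a slope of -0.61 ± 0.23 on the clock score (limma adjusted p = 0.65). In all, 21 genes had a slope on that score, 15 of them outside the clock list.

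Response scores were highest in the A/J and C57BL/6J TG mice, whose WT mice also scored highest (0.032 to 0.082). Set against each strain's own WT mice, the 2 strains exceeded the other 4 by 0.103 ± 0.038 on genes called in those 4, which favours the 4, and by 0.174 ± 0.034 on genes called in all strains but the one scored, which can favour the 2. As the 2 strains were picked from 6 after their scores were seen, 3.94 SE were required, which the first value missed, so chance values of the single WT mice stay open. AKR/J ran against the prone label as the reason, at -0.112 ± 0.056 and -0.206 ± 0.050 from the 2 strains, but only the second passed that bound, so the label was not excluded. A batch that ran with strain is not given in the labels and cannot be told apart.

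Other divisions of the mice were refitted, and the counts of divisions below include the real one. Chance was excluded for TG against WT mice over all strains (3601 genes, highest other 485; of 100 divisions, 1, the real one, called as many), in the prone strains (3172, highest other 1939; 1 of 96, the real one) and in the resistant strains (1444, highest other 223; 1 of 64, the real one). For the 181 strain-dependent genes chance was not excluded (highest other 1872, with 10 of 100 calling as many), but these divisions cannot decide it. They exchange TG and WT mice within strains, so a division can keep the labels of some strains and exchange them in others. The TG effect shared by the strains then counts as a difference between strains. The 6 strains allow too few divisions for a share under 0.05. Prone against resistant TG mice called 1503 (highest other 2351, for A/J, C57BL/6J and 129 against the rest; 5 of 10), the difference of TG effects 64 (highest other 162, the same division; 3 of 10) and WT mice 100 (highest other 207; 8 of 10). With strains as the unit the real division and the highest other both called 0 (10 of 10), and the emphysema label called 965 (highest other 686; 1 of 3, the real one).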

How the results depend on the processing

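The alternatives with 3 mice left out together and with a clock score were chosen only after the result was seen. Counts moved by more than 1.5-fold are given, and the cause was not tested. With every probe set, the difference of TG effects called 17 genes, WT mice 154, 129 264, BALB/cJ 158, C3H 28 and strain dependence 73. Array weights gave 2009 in the prone strains, 4 for the difference of TG effects, 31 in WT mice, 471 in A/J, 86 in AKR/J, 172 in BALB/cJ and 52 for strain dependence. A 2-fold minimum left 58 over all strains, 95 prone, 40 resistant, 4 for the difference, 10 for prone against resistant TG mice, 14 in WT mice, 22 for emphysema, and 277, 45, 218, 67, 49 and 24 in A/J, AKR/J, C57BL/6J, 129, BALB/cJ and C3H. A replicate-number block gave 14 for the difference, 31 in C3H and 98 for strain dependence, but the numbers do not pair the mice (median r -0.02 over 40 same-number pairs). Without a strain term TG against WT called 2242 and Nnt turned to 0.04. Prone against resistant TG mice called 1 with strain as a random block and 42 without strain structure, and 6 strain-level differences called 1. Without 3 mice the resistant strains called 795, the difference 1 and WT mice 204, and F5, P2ry12 and Ppbp were no longer strain-dependent (limma adjusted p = 0.28, 0.97 and 0.14). With the clock score the resistant strains called 897, emphysema 168, BALB/cJ 80 and C3H 64, and the clock list was at -0.01 for emphysema, which follows from adjusting for the mean of its own genes and tests nothing. With an estimated correlation 0 lists held for TG against WT, 1 for the difference (P450), 0 for prone against resistant TG mice and 0 for emphysema, and fry held 2 for the difference and 3 for emphysema. With a mouse or strain left out, counts ran from 2598 to 3682 over all strains, 1821 (without the A/J WT mouse) to 3336 prone, 615 (129) to 1649 resistant, 1 (BALB/cJ) to 425 (AKR/J WT) for the difference, 965 (C57BL/6J TG 1) to 2335 (AKR/J) for prone against resistant TG mice, 0 to 21 (AKR/J) with strains as unit, 30 (C57BL/6J) to 254 (AKR/J WT) in WT mice, 416 (AKR/J) to 1108 for emphysema, 59 (C57BL/6J) to 350 (A/J TG 3) for strain dependence, 1575 to 2204 in A/J, 167 (TG 1) to 414 in AKR/J, 903 (TG 1) to 2161 in C57BL/6J, 226 (TG 3) to 519 in 129, 142 (TG 1) to 436 in BALB/cJ and 16 (TG 2) to 137 in C3H. Left out one at a time, these also moved counts. Prone: A/J 2009, C57BL/6J 1823. Resistant: WT mice of 129 632 and BALB/cJ 786, strain BALB/cJ 700. WT mice: 129 WT 46, A/J TG 3 165, BALB/cJ WT 171, C57BL/6J WT 1 59, strains A/J 160, AKR/J 200, 129 38 and BALB/cJ 169. Emphysema: 129 467. AKR/J: TG 2 178. C3H: TG 1 49, AKR/J 67, C57BL/6J 50. C57BL/6J: WT 1 1248, WT 2 907, TG 2 1203. The difference moved with 18 of 24 mice: 129 TG 2 11 and WT 6, A/J WT 6, TG 2 122 and TG 3 194, AKR/J WT 425, TG 1 11 and TG 2 37, BALB/cJ TG 1 8, TG 2 13, TG 3 128 and WT 23, C3H TG 1 19, TG 2 36 and WT 13, C57BL/6J WT 1 14, WT 2 21 and TG 1 10, and with strains A/J 8, AKR/J 363, C57BL/6J 5, 129 4, BALB/cJ 1 and C3H 15. Strain dependence moved with A/J WT 74, TG 1 95 and TG 3 350, AKR/J TG 1 109 and TG 3 100, BALB/cJ TG 1 111 and TG 2 99, C3H TG 1 115, C57BL/6J WT 1 110, WT 2 103 and TG 1 66, and strains A/J 97, AKR/J 80, C57BL/6J 59 and BALB/cJ 95. List medians turned in sign for complement in prone against resistant TG mice (0.00 without A/J to 0.82 without AKR/J), type 2 genes in the difference (-0.19 without the A/J WT mouse to 0.02 without C57BL/6J) and cell cycle genes for emphysema (-0.22 without 129 to 0.01 without C3H). Strain contrasts without their WT mouse or strain, and BALB/cJ without the 3 mice, were not possible.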

Other observations

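Lists without a shift of their own held genes that moved both ways. Among 11 B and plasma cell genes, the B cell genes Ms4a1 (-0.73 ± 0.20) and Pax5 (-0.69 ± 0.15) fell in TG lungs while Sdc1, a plasma cell surface gene, rose by 0.67 ± 0.06, with 2 higher and 4 lower in all, the same adjusted over the list alone. Of 17 fibroblast and myofibroblast genes 6 rose and 5 fell (6 and 6 adjusted over the list alone), Wnt5a (0.63 ± 0.10) and Aspn (0.55 ± 0.12) upward and Tcf21, a lipofibroblast factor (-0.68 ± 0.09), and Myh11 (-0.52 ± 0.09) downward. TGF-β and BMP pathway genes, which here are ligands, receptors, Smads, antagonists and integrins, rose in 6 of 17 cases and fell in 6 (7 and 6 adjusted over the list alone). Of the ligand genes, Tgfb3 was at 0.65 ± 0.08, Tgfb2 at 0.60 ± 0.07 and Bmp6 at -0.85 ± 0.08, and Bmp2 and Bmp4 did not pass. The Wnt list rose in 6 of 19 cases and fell in 3 (6 and 4 adjusted over the list alone), with Ccn4 at 1.08 ± 0.08, Frzb at 0.82 ± 0.18 and Lef1 at -0.65 ± 0.08. Camera passed none of these lists (adjusted p = 0.51 or higher).

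Antioxidant and macrophage genes were also mixed. Of 11 NRF2 genes 5 fell and 2 rose, the same adjusted over the list alone, with Gstm1 at -0.82 ± 0.11, Gpx2 at -0.67 ± 0.11 and Cat at -0.57 ± 0.07 (camera adjusted p = 0.051). In the alveolar macrophage list Ctsk rose and Fabp4 fell by 1.02 ± 0.17. Fabp4 is also a gene of fat cells, and both measured adipose genes fell, Adipoq by 0.69 ± 0.20 (2 of 2, the same adjusted over the list alone), so the Fabp4 change cannot be laid to macrophages. The adipose score changed most in C3H (-1.29) and C57BL/6J (-0.79), where Fabp4 was at -1.91 and -1.42. It was at -0.40 in A/J and -0.30 in BALB/cJ, with Fabp4 at -1.01 and -0.60. In AKR/J and 129 the adipose score hardly changed (0.01 and -0.03), while Fabp4 was at -0.49 and -0.55. Lcn2, an epithelial and neutrophil lipocalin, rose by 1.24 ± 0.09, and Hdc fell by 0.65 ± 0.15.

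Single mice stood apart in blood cell genes. TG mouse 1 of 129 had S100a8 at 10.96, S100a9 at 11.4, Retnlg at 11.42 and Ly6g at 10.25, where the next highest mice were at 7.9, 8.16, 8.9 and 6.67. The WT mouse of BALB/cJ had Ppbp at 12.58, Pf4 at 9.66 and Rgs18 at 10.72. These mice were named after their values were seen.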
